A study of Mus musculus with 5 samples.

How the data were processed

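Single-colour Agilent arrays (design Agilent-028005, Cy3) were used for peritoneal lavage cells of female BALB/c mice, with 1 array for each of 5 injections, taken 2 h after the injection. Whether RNA of several mice was pooled is not stated. The deposited scanner files hold linear intensity values per the file headers. The authors made them with Agilent Feature Extraction 10.7.1.1, which subtracted background, detrended the signal within each array and set surrogate values for spots near background. No step between arrays had been applied to them. The deposited table of the series holds log2 values, which the authors had quantile-normalized between the 5 arrays. Its scale was worked out from the values, which correlated with the log2 processed signal at 0.9998 or above. Flags per spot in the scanner files are other values of 0 or 1.

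Each array held 62976 spots, of which 3671 were controls and were left out, as were 134 to 219 outlier spots per array. No spot was saturated. The processed signal was taken as log2 and the 75th percentile of each array was subtracted. Spots of the same probe were averaged. Probes were given a gene symbol only where their systematic name was a RefSeq transcript in the annotation of the mouse assembly GRCm38.p6. Of 55681 probes, 26582 had 1 gene symbol by this match, 29099 had none and were left out of the gene comparisons, and none had several. A probe without a match may still measure a known gene. The array files name no genome build, so no coordinates are given. Among 20145 genes, 20121 had a value on every array, and the brightest probe by mean signal stood for a gene where there were several (5354 genes). Replicate spots of a probe on an array had a median SD of 0.043 to 0.060 (log2).

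A gene entered a comparison if its probe was well above background, by the scanner's flag, on at least 1 of the 2 arrays. It was called higher or lower at a difference of at least 2-fold. No test between groups was run, since each group has 1 array and the spread between animals cannot be estimated. The technical SE came from the error given by the scanner for each spot, about 10% of the signal, with a median of 0.204 for a log2 difference. Where a named gene was not well above background on 1 array, its difference is given as a bound ("at least N-fold") computed with the larger of its signal there and the lowest signal that was well above background on that array. Of the genes called higher in AEPS vs PBS, 288 had a further probe above background, of which 181 had one also at least 2-fold higher and 2 had one at least 2-fold lower. For genes called lower there, the numbers with a further probe, the same direction and the opposite direction were 141, 77 and 2. In OVA vs PBS they were 211, 132 and 2 for higher and 57, 24 and 4 for lower genes, and in OVA+AEPS vs OVA 77, 51 and 5, and 66, 29 and 2. In OVA+Alum vs OVA they were 68, 26 and 5, and 139, 78 and 1, and in OVA+AEPS vs OVA+Alum 191, 126 and 2, and 183, 99 and 3. In OVA+AEPS vs AEPS they were 17, 2 and 4, and 14, 1 and 3.

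The 26 gene lists, the comparisons, the thresholds and the rule for named genes were chosen before the data were examined. The lists were chemokines, inflammatory cytokines and growth factors, T helper cytokines, NF-kB responsive genes, immediate early genes, interferon-stimulated genes, inflammasome and pyroptosis, pattern recognition receptors and adaptors, antigen presentation and co-stimulation, complement, eicosanoid synthesis, alternative activation, heat shock and oxidative stress, glycolysis and hypoxia response, cell cycle, housekeeping genes, and markers of neutrophils, inflammatory monocytes, large peritoneal macrophages, small peritoneal macrophages with dendritic cells, B cells, T cells with NK cells, mast cells, eosinophils with basophils, mesothelial with stromal and endothelial cells, and red cells with platelets. Some genes are in more than 1 list. Each list's median was compared with those of 10000 random lists of the same size, matched on signal in 20 bins. Per comparison, the rule named the 8 genes with the largest difference each way among those above background on both arrays, up to 4 members of each list with the largest absolute difference, and 4 housekeeping genes. For AEPS it also named 8 genes each way by the smaller of the 2 AEPS differences. A gene named for 1 comparison could be given in any other.

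Agreement between comparisons was described by Pearson's r and Spearman's rho across genes and by the number of shared genes beside the number that independent lists of those sizes would share. Where 2 comparisons share an array, the values for unchanged groups were simulated 100 times from the technical error. On simulated data, 200 genes were altered by 1.5 or 3 (log2) in either direction. Between 97% and 100% of those altered by 1.5 were recovered per comparison, and between 131 and 174 unaltered genes were called. The simulation held technical error only, and the altered genes were all well above background on both arrays. The recovery thus covers no dim genes, and both values leave out the spread between mice and between arrays. Alternatives were the median of each array, quantile normalization, normexp background correction (offset 50) with quantile normalization, the deposited log2 table, other filters on dim probes, the median over a gene's probes, a 3-fold threshold, a requirement of 3 technical SEs, other control arrays and the mean in place of the list median. Scaling to spike-in probes and the comparisons by slide column were chosen after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.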

Results

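Gene expression was measured in cells washed out of the peritoneal cavity of female BALB/c mice 2 h after an intraperitoneal injection. The injections were PBS (the vehicle), 50 µg AEPS (a polysaccharide from the roots of Actinidia eriantha, a kiwifruit relative), 25 µg OVA (ovalbumin, a model antigen), 25 µg OVA with 50 µg AEPS, or 25 µg OVA with 200 µg alum (an aluminium salt adjuvant). Each of the 5 injections was represented by 1 single-colour array, so no difference below has a replicate check and no p-value is given across genes. Higher and lower describe these arrays only. Values are differences of log2 signal, each with a technical SE from the scanner's error model, which leaves out the spread between mice and between arrays. Between 56.7% and 60.0% of the 55681 probes were well above background on an array, and 15570 genes were so on at least 1 array. The number of arrays limits the precision. Pearson's r between arrays, across genes, which are not independent replicates, lay between 0.98 and 0.99.

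For each fixed gene list the median log2 difference is given relative to the median of all genes in that comparison. A list is called set apart where its median lay among the lowest or the highest 2.5% of 10000 random lists of the same size and signal. This describes these arrays and is not a test. All 5 arrays lay on 1 slide. The PBS array alone lay in row 1 and the other 4 in row 2, so that slide row and treatment cannot be told apart in any comparison with PBS. The PBS and OVA+Alum arrays shared column 4, and 163 genes were at least 2-fold lower on both of them than on each of the other 3 arrays, against 15 genes in the opposite direction. After normexp and quantile normalization there were 86 such genes. The AEPS and OVA+AEPS arrays, which shared the polysaccharide but no column, had 169 genes at least 2-fold higher than on each of the other 3 arrays and 89 lower. A split of this size thus also occurred without a shared column. The 163 genes are called the slide column pattern below, which names the position of the 2 arrays and not a cause. The comparisons of PBS or OVA+Alum with any of the other 3 arrays carry the slide column pattern by definition. Each of the 163 genes differs at least 2-fold there, so their number among the called genes is no separate result. AEPS vs OVA and OVA+Alum vs PBS, which do not cross the sets of columns, are given beside AEPS vs PBS and OVA+Alum vs OVA. The arrays of each of these 2 also differ in the antigen, so neither measures its adjuvant alone.

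**Figure D1:**
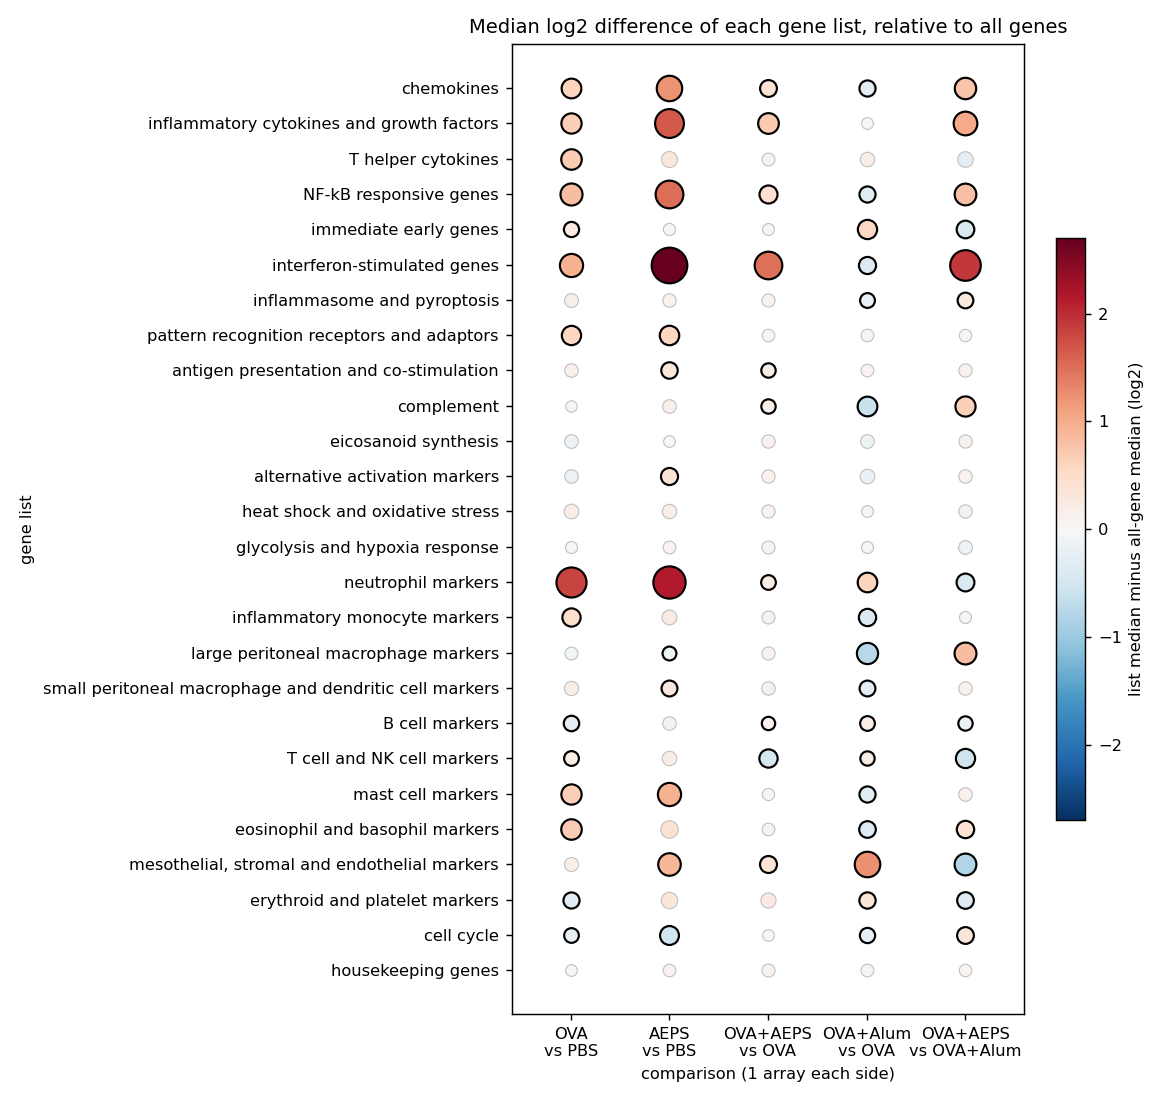
Median log2 difference of each fixed gene list minus the all-gene median (colour and size of the circle), for the 5 comparisons of 1 array with 1 array. Black outlines mark lists set apart from random lists. The interferon-stimulated genes stood 2.69 above all genes in AEPS vs PBS and 1.49 above in OVA+AEPS vs OVA.

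The first comparison set the polysaccharide alone against the vehicle. With AEPS, 39 of 41 measured interferon-stimulated genes were at least 2-fold higher than with PBS and none was lower. Their list median stood 2.69 above that of all genes. Ifit2, Ifit1 and Ifit3, which encode interferon-induced antiviral proteins, were higher by 6.36 ± 0.23, 5.98 ± 0.20 and 5.81 ± 0.20 (log2 difference ± technical SE). Usp18, which encodes a protease that removes the ubiquitin-like protein ISG15, was higher by 4.79 ± 0.20. The gene of the chemokine Cxcl10 was higher by 5.82 ± 0.20, and Edn1, which encodes the vasoconstrictor peptide endothelin-1, by 5.94 ± 0.24. Ifit2 and Edn1 were among the 163 genes of the slide column pattern.

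Inflammatory genes of other lists were also higher with AEPS than with PBS. Of 24 measured chemokines, 12 were at least 2-fold higher and 2 lower, with Ccl4 at 3.13 ± 0.20 and Ccl7 at 2.87 ± 0.20. Of 28 inflammatory cytokines and growth factors, 16 were higher and 2 lower. Il15 was higher by 3.63 ± 0.21, and the alarmin gene Il33, not well above background with PBS, was at least 36.7-fold higher. Of 30 NF-kB responsive genes, 19 were higher (4 of them of the slide column pattern) and none lower, among them Tnfaip3, an inhibitor of this pathway, at 2.41 ± 0.20, and Acod1, which encodes the itaconate-producing enzyme of activated macrophages, at 2.28 ± 0.20. The medians of these 3 lists stood 1.22, 1.66 and 1.51 above that of all genes. Smaller shifts were seen for pattern recognition receptors and adaptors, with 10 of 36 higher (4 of them of the slide column pattern), 3 lower and a median 0.59 above all genes, and for antigen presentation and co-stimulation, with 4 of 30 higher and 0.33 above. The alternative activation list stood 0.38 above all genes, with Socs1 at 2.20 ± 0.20 and Arg1 at -1.45 ± 0.20.

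Cell type markers also differed between the AEPS and PBS arrays. Of 31 neutrophil markers, 22 were at least 2-fold higher and 2 lower with AEPS, and their median stood 2.15 above that of all genes. Lcn2, a siderophore-binding granule protein, was higher by 3.62 ± 0.20. Of 20 mast cell markers, 9 were higher and none lower, 0.97 above all genes. Cpa3, Fcer1a, Mrgprb2 and Mrgprx2 of this list belonged to the slide column pattern. The mesothelial, stromal and endothelial list stood 0.89 above all genes, 0.51 by the mean of its members, with 5 of 21 higher and 2 lower, and the small peritoneal macrophage and dendritic cell list 0.29 above. Large peritoneal macrophage markers stood at -0.15 relative to all genes, with 4 of 32 at least 2-fold lower. Gata6, the transcription factor that defines these macrophages, was lower (-1.39 ± 0.20), as was the retinoic acid receptor gene Rarb (-2.98 ± 0.31). The cell cycle list stood at -0.54, or -0.31 by the mean of its members, with 3 of 26 genes higher and 3 lower. Among the largest differences below PBS were those of Epha2, an ephrin receptor, at -4.87 ± 0.21, Plekhh3 at -3.65 ± 0.21 and Cmklr1, the chemerin receptor, at -3.37 ± 0.29.

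Over all 14936 genes, 1299 were at least 2-fold higher and 1029 lower with AEPS than with PBS, so that 55.8% of these were higher. That share was 51.7% without a filter on dim probes, 68.8% after normexp and quantile normalization and 91.6% when the arrays were scaled to spike-in probes. Of the 163 genes of the slide column pattern, 157 passed the filter on dim probes and were, by definition, among the higher ones. Against the OVA array, which lay in the same set of slide columns, 631 genes were higher and 481 lower with AEPS. There, 37 of 41 interferon-stimulated genes were higher, and their list stood 1.60 above all genes.

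For most other lists, the difference was smaller against OVA than against PBS. AEPS vs OVA leaves out what both arrays share against PBS. Across genes, AEPS vs PBS and OVA vs PBS had an r of 0.75, where technical error with the shared PBS array gave 0.40. Higher in both were 577 genes, where independent lists would share 63.3, and 364 were lower in both (42.8). Of the 577, 157 were of the slide column pattern and higher in both by definition. Neutrophil markers stood 0.41 above all genes in AEPS vs OVA, with 7 of 31 higher and 1 lower, and NF-kB responsive genes 0.41 above, with 2 of 30 higher. Mast cell markers stood at 0.12, with 0 of 20 at least 2-fold different, and were not set apart. Inflammatory cytokines and growth factors stood 0.99 above, with 13 of 27 higher and 1 lower, and chemokines 0.49 above, with 7 of 24 higher and 1 lower. The mesothelial, stromal and endothelial list stood 0.46 above, with 1 of 21 higher and 1 lower, and antigen presentation 0.19 above. Pattern recognition receptors and adaptors stood at 0.0058 relative to all genes, with 1 of 37 higher and 2 lower, and alternative activation markers at 0.020. Small peritoneal macrophage and dendritic cell markers stood at -0.099, and these 3 lists were not set apart either. Large peritoneal macrophage markers stood at -0.050 and the cell cycle list at -0.26.

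The same question was put in the presence of antigen by OVA+AEPS against OVA, which shares no array with the first comparison and involves no array of slide column 4. Again 35 of 41 interferon-stimulated genes were at least 2-fold higher and none lower, with a list median 1.49 above all genes. Ifit2 was higher by 4.08 ± 0.20, Ifit3 by 3.94 ± 0.20, Usp18 by 3.52 ± 0.20 and Tgtp1, which encodes an interferon-induced GTPase, by 3.33 ± 0.22. Cxcl10 was higher by 2.79 ± 0.20 and Ccl7, a monocyte chemoattractant, by 2.57 ± 0.20. Among cytokines, Csf3, which encodes the neutrophil growth factor G-CSF, was higher by 3.14 ± 0.20 and Il23a by 2.32 ± 0.21. Lif was at least 7.89-fold higher, and Csf2 was lower at -2.55 ± 0.22.

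By list, 8 of 24 chemokines, 11 of 28 inflammatory cytokines and growth factors and 3 of 30 NF-kB responsive genes were at least 2-fold higher in OVA+AEPS than in OVA, and 1 cytokine was lower. The 3 lists stood 0.36, 0.70 and 0.46 above all genes. Neutrophil markers stood 0.20 above, with 3 of 31 higher and 3 lower. The mesothelial, stromal and endothelial list stood 0.37 above, and antigen presentation and complement 0.18 above each. The T cell and NK cell list stood at -0.48, with Ncr1, an NK cell receptor, at -1.06 ± 0.20 and Gzmb, which encodes the cytotoxic protease granzyme B, at 1.36 ± 0.20. The B cell list stood 0.11 above all genes by its median and at -0.04 by the mean of its members. Several lists set apart in AEPS vs PBS were not set apart here. Mast cell markers stood at -0.047, pattern recognition receptors and adaptors at 0.063, alternative activation at 0.11 and the cell cycle list at 0.017. Small peritoneal macrophage and dendritic cell markers stood at -0.12 and large peritoneal macrophage markers at 0.10. Genes lower with AEPS in this comparison included the iron exporter gene Slc40a1 (-3.96 ± 0.21) and Pak6 (-4.12 ± 0.33). Pak6 and Gp1bb (-3.24 ± 0.28) were both higher on the OVA array than on the PBS array. By the median over its probes, Gp1bb stood at -0.65 in OVA vs PBS. Among 14904 genes, 608 were higher and 542 lower, 52.9% of these higher. That share was 45.3% with the median of each array, 48.3% with quantile normalization and 66.6% with spike-in scaling. With PBS as the control in place of OVA, 1244 were higher and 927 lower.

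Both AEPS comparisons were set side by side over 14454 genes. Their log2 differences had a Pearson's r of 0.41 and a Spearman's rho of 0.37 across genes. At least 2-fold higher in both were 263 genes, where independent lists would share 38.3, and 156 were lower in both, where they would share 22.5. These numbers were 431 and 45 with spike-in scaling, and 173 and 56 after normexp and quantile normalization. Without a filter on dim probes, r was 0.24. Ranked by the smaller of the 2 differences, Ifit2, Ifit3, Usp18, Ifit3b and the transporter gene Slc10a6 led those higher in both. The cytokine gene Il19 was among the first 8 (4.32 ± 0.21 and 2.83). B3gnt8 (-3.32 ± 0.24 and -2.47) and Arl11 (-2.42 ± 0.26 and -3.23) were among the first 8 of those lower in both.

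**Figure D2:**
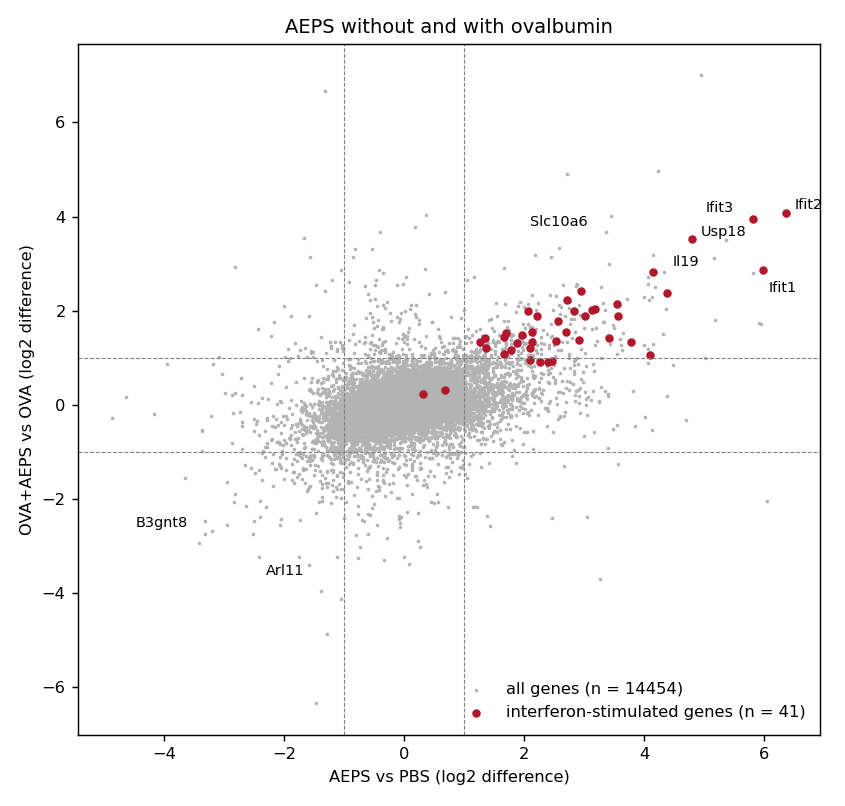
Log2 differences of single genes in AEPS vs PBS (x axis) and in OVA+AEPS vs OVA (y axis), for 14454 genes (grey) and 41 interferon-stimulated genes (red). Dashed lines mark 2-fold. The interferon-stimulated genes lie to the upper right, with Ifit2 at 6.36 and 4.08.

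The AEPS difference was smaller with OVA than without it for several lists. Per gene, the difference with OVA minus that without had a median of -1.10 over the 41 interferon-stimulated genes, -1.90 over the neutrophil markers and -0.71 over the NF-kB responsive genes, against 0.14 over all 15386 genes. With 1 array in each arm, such a value holds the spread between 4 arrays and was not tested. Of these 4, only the PBS array lay in slide row 1 and in column 4, and it enters only the difference without OVA. Slide position and the presence of OVA thus cannot be told apart here. On the arrays themselves, the median of the interferon-stimulated genes stood above PBS by 2.52 with AEPS, 2.45 with OVA+AEPS, 0.82 with OVA and 0.78 with OVA+Alum. For neutrophil markers these values were 1.98, 1.66, 1.68 and 2.37, and for NF-kB responsive genes 1.34, 1.26, 0.70 and 0.64. In these 3 lists, the arrays with AEPS and with OVA+AEPS thus lay closer together than the differences with minus without OVA may imply.

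**Figure D3:**
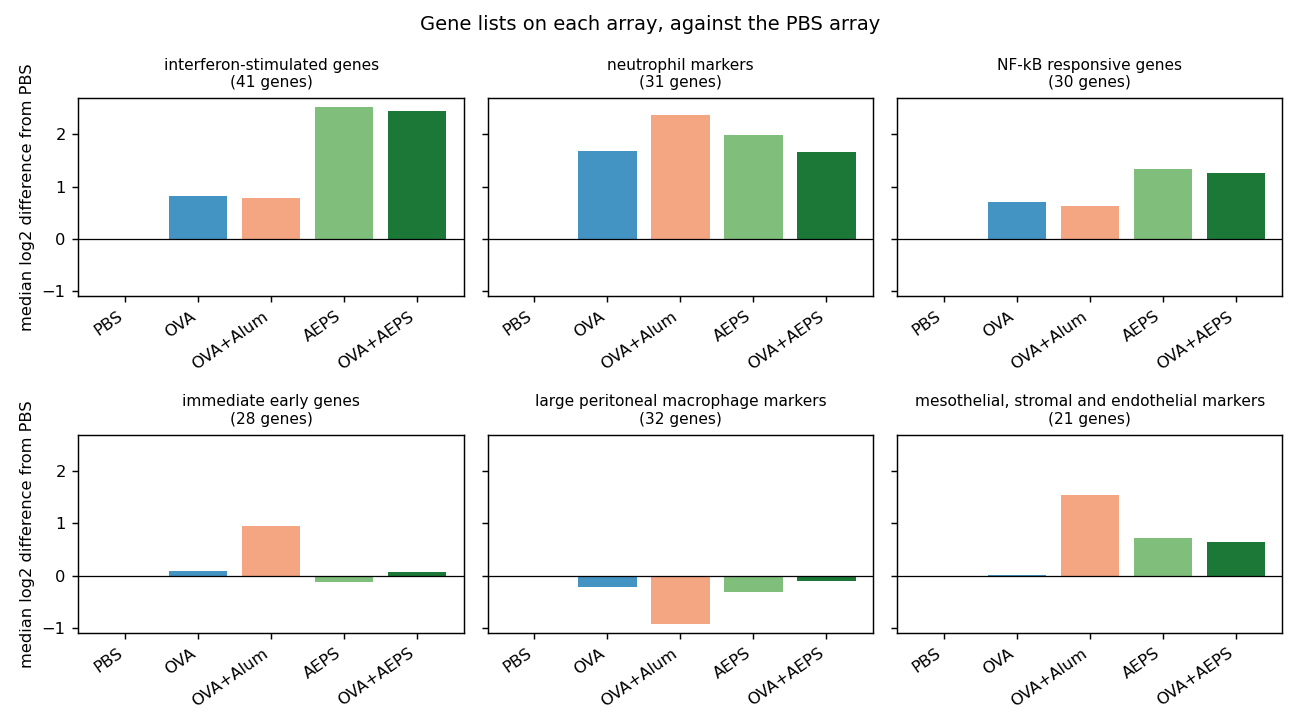
Median log2 difference from the PBS array of 6 gene lists on each of the 5 arrays (bars; 1 array each, so without error bars). Interferon-stimulated genes stood at 2.52 with AEPS and 2.45 with OVA+AEPS, neutrophil markers at 2.37 and mesothelial, stromal and endothelial markers at 1.54 with OVA+Alum.

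Antigen alone was compared with the vehicle. With OVA, 22 of 31 neutrophil markers were at least 2-fold higher than with PBS and none was lower, and the list stood 1.82 above all genes. Cxcr2, the chemokine receptor of neutrophils, was higher by 2.35 ± 0.20 and the collagenase gene Mmp8 by 2.32 ± 0.20. Of 41 interferon-stimulated genes, 18 were higher and none lower, 0.96 above all genes, with Ifih1, a sensor of double-stranded RNA, at 3.03 ± 0.20 and Ifit1 at 2.60 ± 0.20. Cxcl10 was higher by 3.10 ± 0.20 and Edn1, of the slide column pattern, by 4.75 ± 0.24. Of the NF-kB responsive genes, 11 of 30 were higher, 0.84 above all genes, of which Birc2, Bcl2a1d, Tnip3 and Cflar belonged to the slide column pattern.

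Further lists were set apart between the OVA and PBS arrays. Chemokines (6 of 24 higher, 1 lower) stood 0.61 above all genes, inflammatory cytokines and growth factors (12 of 28 higher, 1 lower) 0.66, T helper cytokines (4 of 10 higher) 0.68 and pattern recognition receptors and adaptors (6 of 37 higher, 4 of them of the slide column pattern) 0.57. Inflammatory monocyte markers stood 0.48 above, immediate early genes 0.24 above (1 of 28 higher, 3 lower) and T cell and NK cell markers 0.21 above. Mast cell markers (8 of 20 higher, 4 of them of the slide column pattern) stood 0.66 above, with Cpa3, a mast cell protease gene of that pattern, at 2.19 ± 0.20. Eosinophil and basophil markers (2 of 11 higher) stood 0.69 above. B cell markers stood at -0.26 and the cell cycle list at -0.20, the latter at -0.03 by the mean of its members. Erythroid and platelet markers stood at -0.31, with 6 of 18 at least 2-fold lower, among them Alas2, the first enzyme of haem synthesis in red cell precursors, at -2.07 ± 0.20 and the globin gene Hbb-bs at -1.57 ± 0.20. Epha2 was lower here too (-4.77 ± 0.21). Among genes well above background on both arrays, the largest difference above PBS was that of the claudin gene Cldn22 (5.65 ± 0.30).

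Of 15041 genes, 1003 were at least 2-fold higher and 614 lower with OVA, so that 62.0% of these were higher. That share was 51.3% without a filter on dim probes, 72.6% with the median of each array, 80.1% after normexp and quantile normalization and 82.9% with spike-in scaling. All 163 genes of the slide column pattern were, by definition, among the higher ones. OVA and PBS cannot be compared within a set of slide columns. With AEPS present on both sides, OVA+AEPS against AEPS, 303 genes were higher and 276 lower of 14692. These numbers were 89 and 112 among genes well above background on both arrays. The neutrophil list stood at -0.39 relative to all genes. Across 14347 genes, OVA vs PBS and OVA+AEPS vs AEPS, which share no array, had an r of -0.0038. At least 2-fold higher in both were 25 genes, 49 were lower in both and 54 differed in opposite directions. Each of these numbers was above that for independent lists. Of these comparisons, only OVA vs PBS crosses the slide rows and the sets of slide columns.

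The response to alum was examined by OVA+Alum against OVA. Of 21 mesothelial, stromal and endothelial markers, 13 were at least 2-fold higher with alum and 1 lower, and the list stood 1.23 above all genes, 0.64 after normexp and quantile normalization. The mesothelial marker genes Upk3b and Lrrn4 were higher by 2.13 ± 0.22 and 2.10 ± 0.35, and Lum, which encodes an extracellular matrix proteoglycan, by 1.81 ± 0.22. Neutrophil markers stood 0.60 above, with 7 of 31 higher and 1 lower, and immediate early genes 0.57 above, with 6 of 28 higher and none lower. The transcription factor genes Fosb and Fos were higher by 1.45 ± 0.21 and 1.26 ± 0.20. F3, which encodes tissue factor, the initiator of coagulation, and the thrombomodulin gene Thbd were higher by 2.15 ± 0.20 each. The stress cytokine gene Gdf15 was higher by 2.25 ± 0.26 and Hmox1, the haem-degrading enzyme, by 1.49 ± 0.20.

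Large peritoneal macrophage markers were lower with alum than with OVA alone. Of 32, 8 were at least 2-fold lower and none higher, and the list stood at -0.76 relative to all genes. The scavenger receptor gene Marco was at -1.80 ± 0.20, the complement receptor gene Vsig4 at -1.43 ± 0.20 and Timd4, a receptor for apoptotic cells, at -1.26 ± 0.20. Complement genes stood at -0.61, with 5 of 21 lower and 2 higher. Inflammatory monocyte markers stood at -0.40, small peritoneal macrophage and dendritic cell markers at -0.28, and eosinophil and basophil markers at -0.35. Interferon-stimulated genes stood at -0.38 with 2 of 41 lower, NF-kB responsive genes at -0.31 with 4 of 30 lower, and chemokines at -0.31 with 1 of 24 higher and 2 lower. Inflammatory cytokines and growth factors went both ways, with 6 of 27 higher, 5 lower and a list median of 0.019 relative to all genes. Of these, Il6 and Il1a were lower (-1.98 ± 0.20 and -2.44 ± 0.20), and Ifnb1, not well above background with alum, was at least 4.97-fold lower. The inflammasome list stood at -0.21, with the caspase genes Casp1 and Casp4 at -1.72 ± 0.20 each. Mast cell markers stood at -0.31, with 4 of 20 lower, and the cell cycle list at -0.24, or -0.45 by the mean of its members. Casp1, Casp4, Il1a, Ifnb1, the 4 NF-kB responsive genes and the 4 mast cell markers belonged to the slide column pattern. B cell markers stood 0.21 above all genes, with 0 of 30 at least 2-fold different, and erythroid and platelet markers 0.32 above, with 6 of 17 higher and 1 lower. T cell and NK cell markers stood at 0.18 by their median and 0.022 by the mean of the members, with 0 of 36 higher and 4 lower.

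Of 15060 genes, 625 were at least 2-fold higher and 820 lower with alum, 43.3% of these higher, and 30.5% after normexp and quantile normalization. The 163 genes of the slide column pattern were, by definition, all among the lower ones. Against PBS, which shared the slide column with OVA+Alum, 974 genes were higher and 776 lower. OVA+Alum vs PBS holds the antigen as well as alum, and neutrophil markers already stood 1.82 above all genes in OVA vs PBS. There the mesothelial, stromal and endothelial list stood 1.60 above all genes with 14 of 21 higher, neutrophil markers 2.43 above with 24 of 31 higher and 2 lower, and immediate early genes 1.02 above with 14 of 28 higher. Large peritoneal macrophage markers stood at -0.86 with 15 of 32 lower. Complement and cell cycle lists stood at -0.75 and -0.53. The inflammasome list at -0.052 and T cell and NK cell markers at 0.20 were not set apart there.

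Some lists below all genes in OVA+Alum vs OVA were set apart above them in OVA+Alum vs PBS. Interferon-stimulated genes stood at 0.84 relative to all genes, NF-kB responsive genes at 0.70, chemokines at 0.47 and mast cell markers at 0.38. In OVA vs PBS, without alum, the same lists stood at 0.96, 0.84, 0.61 and 0.66. The change of sign thus comes with the antigen in the comparison and is no measure of alum alone. Further lists set apart against OVA were not set apart against PBS. Eosinophil and basophil markers stood at 0.36, inflammatory monocyte markers at 0.13 and small peritoneal macrophage and dendritic cell markers at 0.053. B cell markers stood at -0.039 and erythroid and platelet markers at -0.19.

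Both adjuvants were compared directly by OVA+AEPS against OVA+Alum. With AEPS, 38 of 41 interferon-stimulated genes were at least 2-fold higher than with alum and none was lower, and the list stood 1.90 above all genes. Ifit2 was higher by 5.46 ± 0.21 and Ifit3 by 4.66 ± 0.20. Inflammatory cytokines and growth factors stood 1.02 above, with 13 of 28 higher and 2 lower. Il6 was higher by 3.36 ± 0.20, Il1a by 3.23 ± 0.20, and Lif and Ifnb1, the interferon beta gene, by at least 10.1-fold and 5.74-fold. Ifit2, Il1a and Ifnb1 belonged to the slide column pattern. Chemokines stood 0.77 above, with 9 of 24 higher and none lower, led by Cxcl10 (3.64 ± 0.20) and the B cell chemoattractant gene Cxcl13 (2.57 ± 0.20). NF-kB responsive genes stood 0.80 above, with 9 of 30 higher, 4 of them of the slide column pattern. Large peritoneal macrophage markers stood 0.82 above, with 12 of 32 higher and Marco at 2.55 ± 0.20, and complement 0.65 above, with 7 of 21 higher and 1 lower. The inflammasome list stood 0.27 above, with 2 of 24 higher and 1 lower, and the cell cycle list 0.36 above, with 5 of 28 higher. The eosinophil and basophil list stood 0.40 above, with 1 of 11 higher. Casp1 and Casp4 of the inflammasome list and Mki67 and Nusap1 of the cell cycle list belonged to the slide column pattern.

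Other lists were lower with AEPS than with alum. Immediate early genes stood at -0.43 relative to all genes, with 9 of 28 lower and 2 higher, and Egr1 at -2.43 ± 0.20. Mesothelial, stromal and endothelial markers stood at -0.82, or -0.54 after normexp and quantile normalization, with 8 of 21 lower and 1 higher, and neutrophil markers at -0.44, with 7 of 31 lower and 2 higher. Mmp9 and Cxcr2 were at -2.06 ± 0.20 and -2.04 ± 0.20, and the interferon-inducible Slfn4 of the same list was at 1.80 ± 0.20. T cell and NK cell markers stood at -0.57 with 6 of 35 lower and 1 higher, B cell markers at -0.18 with 3 of 30 lower, or -0.29 without a filter on dim probes, and erythroid and platelet markers at -0.35. Slc40a1 (-4.56 ± 0.21), Arl11 (-4.02 ± 0.29) and the gasdermin gene Gsdme (-3.64 ± 0.20) were among those with the largest differences below alum, and all 3 were also lower with AEPS when compared with OVA alone. In total 1014 of 14994 genes were higher and 966 lower, 51.2% of these higher. That share was 41.6% with the median of each array, 48.7% with quantile normalization and 66.2% with spike-in scaling. Of the slide column genes, 156 passed the filter on dim probes and were, by definition, among the higher ones. No pair of arrays within a set of columns makes this comparison.

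The overlap between the adjuvants was examined over 14731 genes by setting OVA+Alum vs OVA against OVA+AEPS vs OVA. Pearson's r across genes was 0.45, but both comparisons use the OVA array, and unchanged groups simulated against it from the technical error gave 0.39. The covariance was 0.20 against a simulated 0.029. Among genes well above background on all arrays used, r was 0.15. At least 2-fold higher in both were 106 genes, where independent lists would share 14.9, and 206 were lower in both, where they would share 30.2. These numbers were 55 and 56 among genes well above background on all arrays used, and 15 and 71 after normexp and quantile normalization. Unchanged groups simulated against the shared array gave 20.3 genes at least 2-fold different the same way, higher and lower together, from technical error alone, which leaves out the spread between mice and arrays. With AEPS vs PBS, which shares no array with the alum comparison but crosses slide columns in the opposite direction, r was -0.16. There, 291 genes were at least 2-fold different in opposite directions, where independent lists would give 81.0, while 101 were higher in both, where they would share 38.6, and 47 lower in both, where they would share 39.2. Of the 291, 157 were genes of the slide column pattern, which go in opposite directions here by definition. The excess over 81.0 is therefore in part fixed in advance.

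Comparisons that neither share an array nor cross the sets of slide columns gave values of r near 0. Each pair uses OVA+Alum vs PBS, which holds the antigen as well as alum and crosses the slide rows. In AEPS vs OVA the antigen is on the opposite side of the difference, which can lower r. These values thus do not measure the overlap between the adjuvants alone. Between OVA+Alum vs PBS and OVA+AEPS vs OVA, r was 0.058. There, 123 genes were higher in both, where independent lists would share 29.0, 41 lower in both, where they would share 17.5, and 133 different in opposite directions, where they would give 45.2. Between OVA+Alum vs PBS and AEPS vs OVA, r was 0.086, with 113 genes higher in both, where independent lists would share 29.2, 51 lower in both (14.4) and 81 in opposite directions (41.0).

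Eicosanoid synthesis, heat shock and oxidative stress, glycolysis and hypoxia response, and housekeeping genes were set apart in none of the 5 comparisons, with list medians between -0.14 and 0.20 relative to all genes. Actb differed by -0.23 to 0.16 and Gapdh by -0.43 to -0.06 in these comparisons, while Hprt stood at 0.73 ± 0.20 in OVA vs PBS and -0.94 ± 0.20 in OVA+Alum vs OVA.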

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

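Apart from the test of array scaling, the tests in this part were chosen only after the results they address were seen. A difference between groups drew attention to 61 genes that were at least 2-fold higher in AEPS vs PBS or in OVA+AEPS vs OVA and at least 2-fold lower in the other. Independent lists would give 58.9, and the difference between the comparisons was not tested. A signal in data left out of the gene comparisons was seen in 260 of 13738 probes without a gene symbol by the RefSeq match. These were at least 2-fold higher in both AEPS comparisons, where independent lists would share 43.7.

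A first pattern is the 163 genes lower on the PBS and OVA+Alum arrays, which shared a slide column, than on the other 3 arrays. Scaling of the arrays as the whole cause is argued against by 173 such genes under quantile normalization, although 86 were found after normexp background correction with quantile normalization. A response shared by the AEPS, OVA and OVA+AEPS arrays may contribute, since 25 of the genes belong to the fixed lists, where 6.41 would be expected, but zinc finger (Zfp) genes outside the lists were also frequent (15, with 3.31 expected). For RNA or labelling quality, probes of the same gene disagreed by a median of 0.173 (log2) between PBS and OVA+Alum. The values were 0.151 to 0.199 between these and the other arrays, and 0.142 to 0.153 among the other 3. Quality as the cause would make the gap between PBS and OVA+Alum smaller than those to the other arrays, but it lay within their range. The gap between probes grows with any difference between arrays, so it cannot decide this. Slide column, handling and treatment cannot be told apart here, because each treatment has 1 array.

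A second pattern is the higher mesothelial, stromal and endothelial transcripts with alum. A lower share of macrophages raising all other cell types alike is argued against on these 2 arrays. The median of this list exceeded that of the B cell list by 1.03 in OVA+Alum vs OVA (95% bootstrap interval over members 0.49 to 1.29). It exceeded the T and NK cell, mast cell and neutrophil lists by 1.05, 1.54 and 0.63, the last with an interval of 0.017 to 1.02. In OVA+Alum vs PBS it lay below the neutrophil list (-0.84) and above the others. These intervals resample genes and leave out the spread between mice and arrays. After normexp and quantile normalization the list stood 0.64 above all genes, in place of 1.23. Lining cells carried over when the lavage was collected stay open, since the 13 members at least 2-fold higher would be seen with carry-over and with a response to alum alike. With 1 array these cannot be told apart, and the response to alum is an untested biological explanation.

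A further pattern is the lower neutrophil and interferon-stimulated transcripts on the PBS array than on the OVA array. Brightness of the PBS array, which would move genes of like signal alike, is argued against as the whole cause only by the result that set these lists apart. The list medians lay 1.80 and 0.94 above the median of random lists of the same signal, whose SDs were 0.074 and 0.065. These are the random lists by which both lists had already been called set apart, so no separate test was made. An atypical PBS array, or its place as the only one in its slide row, stays open, since the neutrophil list stood at least 1.66 above PBS on each of the other 4 arrays, as it also would if each injection had raised it. The OVA preparation itself stays open too, although the neutrophil list stood at -0.39 relative to all genes in OVA+AEPS vs AEPS, because the effects of antigen and polysaccharide need not add and each arm has 1 array. These explanations cannot be told apart with 1 PBS array.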

How the results depend on the processing

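Scaling to spike-in probes, the comparisons by slide column and the alternatives for the list differences between AEPS with and without OVA were chosen after seeing the data. With 1 array per group no replicate could be left out and no paired analysis was possible. Signal over background limits dim genes, whose differences move with the filter and the background correction. The all-gene median moved by over 0.1 (log2) with the median of each array, by 0.12 in OVA vs PBS and -0.10 in OVA+AEPS vs OVA+Alum. With spike-in scaling it moved by 0.29 in OVA vs PBS, 0.66 in AEPS vs PBS, 0.16 in OVA+AEPS vs OVA and 0.17 in OVA+AEPS vs OVA+Alum. Of 162 values of 17 counts and correlations under alternatives, 104 stayed within 1.5 times a count or close to a correlation. Of 928 values for gene lists, 912 stayed close, and of 635 for named genes, 560 did so. Of the rest for named genes, 74 moved in size and 1 had the opposite sign: Gp1bb in OVA vs PBS, at -0.65 by the median over probes. Except where the alternative itself counts fewer or more genes (the thresholds and filters), the cause was not tested. Close meant within 0.1 for a correlation, within a bootstrap spread over members for a list and within the technical error for a gene. Some values could not move. The median of each array shifts all genes of an array alike, which leaves lists relative to all genes and correlations unchanged. Spike-in scaling likewise leaves correlations unchanged, and the median over probes leaves genes with 1 probe unchanged.

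With normexp and quantile normalization, genes higher and lower numbered 511 and 127 in OVA vs PBS, 773 and 351 in AEPS vs PBS, 260 and 212 in OVA+AEPS vs OVA, 153 and 349 in OVA+Alum vs OVA, and 494 and 456 in OVA+AEPS vs OVA+Alum. Both AEPS comparisons then had an r of 0.53 across genes, with 173 genes higher and 56 lower in both, and AEPS and alum an r of 0.13, with 15 and 71. With spike-in scaling, the numbers were 1596 and 330 in OVA vs PBS, 3284 and 303 in AEPS vs PBS, and 431 and 45 in both AEPS comparisons. At 3-fold, they were 407 and 207 in OVA vs PBS, 620 and 332 in AEPS vs PBS, 278 and 253 in OVA+AEPS vs OVA, 178 and 340 in OVA+Alum vs OVA, and 405 and 314 in OVA+AEPS vs OVA+Alum. With more than 3 technical SEs, 409 were lower in OVA vs PBS.

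Well above background on both arrays, 347 genes were lower in OVA vs PBS, 674 lower in AEPS vs PBS, 385 higher and 309 lower in OVA+AEPS vs OVA, and 396 higher in OVA+Alum vs OVA. On all arrays used, AEPS and alum had an r of 0.15, with 55 genes higher and 56 lower in both. Without a filter, 1126 were lower in OVA vs PBS, 1009 higher in OVA+AEPS vs OVA and 1003 higher in OVA+Alum vs OVA. Both AEPS comparisons then had an r of 0.24, and 289 genes were higher with AEPS and alum. With OVA as the control of AEPS, 631 were higher and 481 lower, and with the mean of PBS and OVA, 830 and 664. With PBS as the control, 1244 were higher and 927 lower for OVA+AEPS, and 974 higher for OVA+Alum. AEPS and alum had a Spearman's rho of 0.16, and with AEPS vs PBS the r was -0.16, with 47 genes lower in both.

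For lists relative to all genes, the mean of the members gave 1.32 for neutrophil, -0.22 for large macrophage and -0.027 for cell cycle lists in OVA vs PBS. In AEPS vs PBS it gave -0.29 for B cell, 0.51 for mesothelial and -0.31 for cell cycle lists, in OVA+AEPS vs OVA -0.036 for B cells, and in OVA+Alum vs OVA 0.022 for T and NK cells and -0.45 for cell cycle. Without a filter, housekeeping genes stood at -0.037 in AEPS vs PBS, large macrophage markers at 0.017 in OVA+AEPS vs OVA and B cell markers at -0.29 in OVA+AEPS vs OVA+Alum. By the median over probes, housekeeping genes stood at -0.028 in OVA+AEPS vs OVA. With normexp and quantile normalization, mesothelial markers stood at 0.64 in OVA+Alum vs OVA and -0.54 in OVA+AEPS vs OVA+Alum, and the AEPS difference with minus without OVA was -1.71 for neutrophil markers. The slide column pattern held 86 genes with that normalization and 290 with spike-in scaling.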

Other observations

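The genes in this part were chosen after their values were seen. Values are given for 5 interferon-inducible genes outside the fixed list, with no count or test of such genes as a group. Ifi209 and Ifi214, of the Ifi200 family of nucleic acid sensors, differed by 4.13 and 4.06 (log2) in AEPS vs PBS and by 2.29 and 2.71 in OVA+AEPS vs OVA. Eif2ak2, which encodes the RNA-activated kinase PKR, differed by 3.71 and 2.25, and the GTPase gene Tgtp2 by 4.08 and 2.22. Ifi211 differed by 3.14 in AEPS vs PBS and by 3.06 in OVA vs PBS, but by 0.29 in OVA+AEPS vs OVA. Ifi209, Ifi211, Ifi214 and Eif2ak2 belonged to the slide column pattern, and against PBS on the OVA+Alum array they differed by 0.39, 0.24, -0.12 and 0.03.

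Some red cell transcripts differed between arrays. Alas2 and the globin gene Hbb-bs stood at -2.07 and -1.57 in OVA vs PBS and at -2.31 and -1.61 in OVA+AEPS vs AEPS. They stood at 1.06 and 0.73 in AEPS vs PBS, at 0.83 and 0.69 in OVA+AEPS vs OVA and at 3.13 and 2.30 in AEPS vs OVA. The erythroid and platelet list stood at 0.33 and 0.24 relative to all genes in AEPS vs PBS and OVA+AEPS vs OVA and was not set apart there. Of this list, 6 of 18 members were at least 2-fold lower and 1 higher in OVA vs PBS and 6 of 16 lower in OVA+AEPS vs AEPS, while in OVA+Alum vs PBS 1 of 18 was lower and 1 higher, and the list was not set apart. In OVA+AEPS vs AEPS, T cell and NK cell markers stood at -0.49 relative to all genes, erythroid and platelet markers at -0.54, and cell cycle and immediate early genes at 0.23 and 0.17.

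On 1 array alone, 202 genes were at least 2-fold higher with PBS than on each of the other 4 arrays and 236 lower. These numbers were 175 and 52 with AEPS, 161 and 61 with OVA, 145 and 35 with OVA+AEPS, and 159 and 116 with OVA+Alum. Among genes well above background on all arrays, the higher ones numbered 96 with PBS, 43 with AEPS, 31 with OVA, 37 with OVA+AEPS and 88 with OVA+Alum. After scaling to the 75th percentile, the mean of 8 spike-in probes deviated from its mean over the arrays by 0.34 (log2) on the PBS array, -0.32 with AEPS, 0.04 with OVA, -0.12 with OVA+AEPS and 0.06 with OVA+Alum.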
